A study of Mus musculus with 4 samples.

How the data were processed

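RNA was measured in 4 libraries from WW6 mouse embryonic stem cells, 2 transfected with small interfering RNA against GFP (control) and 2 against Kdm5b (knockdown). Per the labels' protocols, Trizol RNA was depleted of ribosomal RNA, copied with oligo-dT and random primers, marked for strand with dUTP and sheared to fragments of 300 bp. The authors deposited 1 table of FPKM (fragments per kilobase of transcript, scaled to the fragments mapped) per locus and library, and per the submitters' processing notes Cufflinks and Cuffdiff were used with the mm9 build. Their versions, the aligner and whether strand was used in counting are not given in the sources used here, so a gene and an overlapping or antisense partner may share fragments, and 4428 loci share an interval with another. FPKM of a transcript shorter than a fragment is unstable, since 1 fragment is then worth a large value, and an exact 0 can be a failed estimate.

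Loci were named from their RefSeq identifiers with a table of the GRCm38.p6 assembly, used for names only. It gave 1 symbol to 23241 of 23697 loci, several to 189 and none to 267. Coordinates are those of the deposited table. Of 289 entries on 20 gene lists, 278 were found.

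Depth was estimated because FPKM carries no totals. In genes with a known transcript length the low values fell in steps, and 78.3% to 80.9% of low values lay within 0.15 of a whole number of fragments. The steps put control A, knockdown A and knockdown B at 102%, 76.6% and 98.5% of the depth of control B. In control A, control B, knockdown A and knockdown B, 1 FPKM in a transcript of 2000 bp stands for 7.95, 7.77, 5.95 and 7.65 fragments. These are estimates, so no counting interval was made from them.

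Loci with a mean of at least 1 FPKM over the 4 libraries were tested on log2(FPKM + 1), a scale that understates the change of low genes, with limma 3.58.1 (linear model on group alone, eBayes with trend) in R 4.3.3. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Gene lists with at least 3 tested members (18) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Levels, splits of the libraries, correlations and medians by level were described without a test. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and sequences were compared with BLAST 2.17.0.

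The test, its samples, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule names Kdm5b, the other H3K4 demethylases, the 10 genes with the smallest p on each side among those whose knockdown libraries both lie outside the control range, called or not, and 2 to 4 members of each list by largest absolute log2 fold change. Names of microRNAs, small nucleolar and nuclear RNAs, 5S ribosomal RNA, and unnamed Gm and Rik models were tested but skipped when the 10 were picked. Where a symbol had several rows the one with the highest mean stood for it in lists.

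The fit was tested on simulated data with 200 genes changed in known directions, drawn at the estimated depths with a dispersion of 0.04. That dispersion was a set value, not estimated from these libraries, so the shares recovered may not hold for them. With each fragment its own molecule, 9% of genes changed by 1 log2 unit were recovered, 92.5% at 2 and 95.5% at 3, over 11319, 11292 and 11312 genes. In that simulation 18.2%, 9.31% and 16.6% of the calls were false, above the 5% that the threshold is meant to allow, and a limit first set on that share was not met and was dropped. A second simulation was added after this was seen, with molecules read several times (11.2 copies in knockdown replicate A). The copies were set so that control A and the knockdown libraries gained their observed shares of zeros. Control B, on which the loci for those shares were chosen, took the mean of control A and knockdown B. The second simulation recovered 0%, 30.5% and 79.5% over 11175, 11170 and 11173 genes, with 0, 0 and 2 false calls. In it no value of knockdown A above 0 could fall under 11.2 fragments. In the data 256 loci of knockdown A lay at the step of 1 fragment, so these counts of false calls may not hold for the libraries. All recovered genes had the right direction in both simulations. Most changes of 2-fold were not recovered in either. In the data themselves Kdm5b, at a log2 fold change of -2.14, was not called.

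Alternatives were pseudocounts of 0.1 and 0.01, no filter and a filter at 5 FPKM, leaving out small noncoding RNA genes, upper-quartile scaling, quantile normalization, eBayes without trend, robust eBayes, the replicate letter as a block, each library left out, an estimated correlation and fry for lists, and a smaller cut for fold changes. Loci with a mean of at least 20 estimated fragments and library weights estimated by limma were added after seeing the data.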

Results

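RNA levels were measured in mouse embryonic stem cells of the WW6 line after transient transfection with small interfering RNA against Kdm5b, a demethylase that removes methyl groups from lysine 4 of histone H3. Control cells received small interfering RNA against GFP. Total RNA was depleted of ribosomal RNA and turned into strand-marked libraries, 2 from control cells and 2 from knockdown cells, named replicates A and B in each group. The deposited values were FPKM for 23697 loci, of which 6525 stood at 0 in all 4 libraries and 11784 had a mean of at least 1 FPKM and were tested. From the steps between the lowest values, a tested locus held an estimated median of 144 and 137 fragments in control replicates A and B, and 103 and 135 in knockdown replicates A and B; knockdown replicate A had 76.6% of the depth of control replicate B. Knockdown replicate A listed 11953 loci at 0, against 8131 and 8281 in the controls and 8609 in knockdown replicate B. The labels do not say that A and B were separate cultures, so the p-values below measure only the spread between these libraries, which may be technical.

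The first question was how far Kdm5b itself was lowered. Kdm5b (NM_152895; mm9 chromosome 1, 136456754 to 136529455) stood at 99.7 and 145 FPKM in the controls and at 22.7 and 31.1 FPKM in the knockdown libraries. The means were 122 ± 32.1 FPKM (SD, n = 2) and 26.9 ± 5.91 FPKM (SD, n = 2), so the knockdown mean was 22.0% of the control mean. Both knockdown libraries lay below both controls, with a log2 fold change of -2.14 on the log2(FPKM + 1) scale (standard error 0.30, 95% interval -2.86 to -1.42). Of the other demethylases of this histone mark, Kdm5a, Kdm5c, Kdm1a and Kdm1b were measured, and none passed the limma test. Their log2 fold changes were -0.39 for Kdm5a (standard error 0.33), -0.07 for Kdm5c (0.24), 0.27 for Kdm1a (0.25) and 0.17 for Kdm1b (0.33). Each moved by more than 1.5 times when 1 library was left out. Without knockdown replicates A and B the values were -0.09 and -0.70 for Kdm5a and -0.15 and 0.02 for Kdm5c, and without control replicates A and B they were 0.05 and 0.50 for Kdm1a and 0.07 and 0.26 for Kdm1b. Kdm5a and Kdm1b each share a locus interval with another gene, and Kdm5d was listed at 0 in all 4 libraries. Kdm5b ranked 7 by limma p among the tested loci, but its limma adjusted p was 0.562, so the targeted gene itself did not pass the threshold of 0.05.

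**Figure D1:**
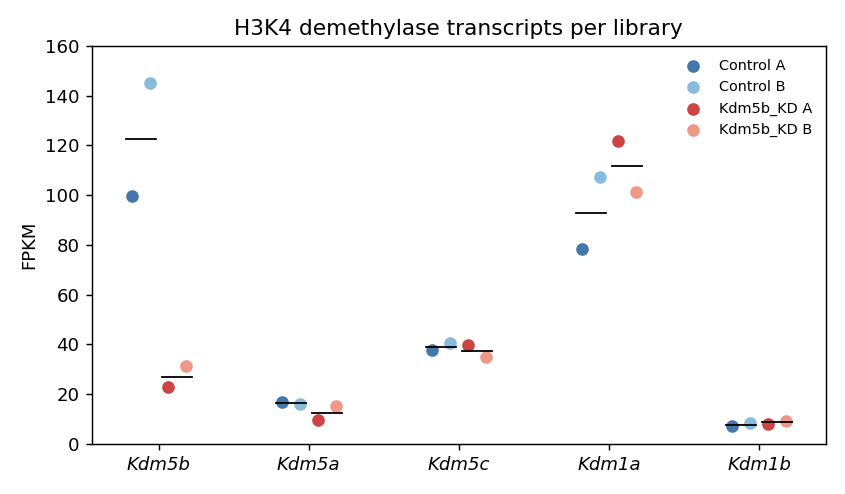
FPKM (vertical axis) of Kdm5b and the other measured H3K4 demethylases in each library; each point is 1 library and each black line a group mean over 2 libraries. Kdm5b lies at 99.7 and 145 FPKM in the controls and at 22.7 and 31.1 FPKM in the knockdown libraries.

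The main comparison asked whether RNA levels differed between knockdown and control cells. Of 11784 loci tested, 4 were lower and 0 were higher in the knockdown libraries at a limma adjusted p under 0.05; at an unadjusted p under 0.05 the counts were 176 lower and 114 higher, together fewer than the 589 that chance alone gives at that threshold. The 4 are Lars2, a mitochondrial leucyl-tRNA synthetase, and the microRNA loci Mir6236, Mir3960 and Mir3070b, which fall outside the rule for named genes and are named because they make up the count. Lars2 (mm9 chromosome 9, 123276057 to 123371782) fell from 1754 and 3176 FPKM in the controls to 113 and 103 FPKM, a log2 fold change of -4.44 (standard error 0.32, limma adjusted p = 0.0228). Mir6236 fell from 44098 and 82682 FPKM to 1875 and 1813 FPKM (log2 fold change -5.03, standard error 0.36, limma adjusted p = 0.0228). A line through control A and the knockdown mean, chosen after the values were seen, predicted Lars2 in control B from Mir6236 to within 2.56%. That line tests this 1 value only. Mir3960 was listed at 209 and 214 FPKM in the controls and Mir3070b at 110 and 113 FPKM, and both were listed at 0 in both knockdown libraries, with limma adjusted p of 0.00149 and 0.00265. Both loci, like Mir6236, are shorter than the fragments, so 1 fragment weighs heavily. The control values of Mir3960 and of Mir3070b each stood in the ratio 0.977, that of the worth of 1 fragment in control A to control B. Both controls thus held an equal whole number of fragments of each, and the small spread behind these p-values reflects that. No call held without either control library: 0 loci were called without control replicate A and 0 without control replicate B, while the log2 fold changes stayed large, at -4.87 and -4.01 for Lars2, -5.49 and -4.58 for Mir6236, -7.75 and -7.72 for Mir3960 and -6.83 and -6.80 for Mir3070b. The count of calls was 1, Lars2, when small noncoding RNA genes were left out, and 1, Mir3960, with no filter on low values.

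Among the 10 genes with the smallest p on the lower side were Ezr, which links the cell membrane to actin, Clic4, an intracellular chloride channel protein, Shmt2, the mitochondrial serine hydroxymethyltransferase, and Agpat1, an enzyme of phosphatidic acid synthesis. Ezr stood at 88.3 ± 15.4 FPKM in controls and 34.8 ± 4.72 FPKM in knockdown libraries (SD, n = 2 each), and Clic4 at 66.5 ± 19.3 and 27.2 ± 1.00 FPKM. Shmt2 stood at 73.8 ± 4.04 and 36.4 ± 4.16 FPKM, and Agpat1 at 27.3 ± 1.85 and 8.81 ± 0.05 FPKM. Cubn, an endocytic receptor, had a log2 fold change of -2.34 (standard error 0.55) and the snoRNA host transcript Snhg20 one of -1.46 (standard error 0.34). Smim22 was listed at 10.7 and 5.5 FPKM in the controls, and Lsm7, a part of the RNA-binding Lsm ring, at 5.08 and 7.80 FPKM. In controls A and B these values stand for only an estimated 9.80 and 4.72 fragments of Smim22 and 6.20 and 9.03 of Lsm7. Both genes were listed at 0 in both knockdown libraries. With Lars2 and Kdm5b these made up the 10. On the higher side, Tmsb4x, which binds actin monomers, stood at 300 ± 116 FPKM in controls and 824 ± 209 FPKM in knockdown libraries. Ndufs5 and Ndufa12, subunits of respiratory complex I, had log2 fold changes of 1.34 and 0.85 (standard errors 0.32 and 0.22) and the assembly factor Ndufaf2 one of 0.98 (standard error 0.24). Over 47 tested genes named Nduf the median was 0.11. It was -0.01 and 0.39 without knockdown replicates A and B, and -0.0046 and 0.31 without control replicates A and B. The assembly factor Ndufaf3, named after its values were seen, stood at -1.12 (standard error 0.34). Chromogranin A (Chga) had a log2 fold change of 1.35, the ubiquitin-like modifier Urm1 0.91, the interferon-inducible GTPase Irgm1 1.59, and Epp13, Zbtb11os1 and the noncoding transcript Platr14 1.30, 1.70 and 1.03. Except for Lars2, none of these 20 genes passed the limma threshold, and the limma adjusted p of those other than Kdm5b was 0.918. Agpat1, Shmt2, Snhg20 and Zbtb11os1 share a locus interval with another gene.

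**Figure D2:**
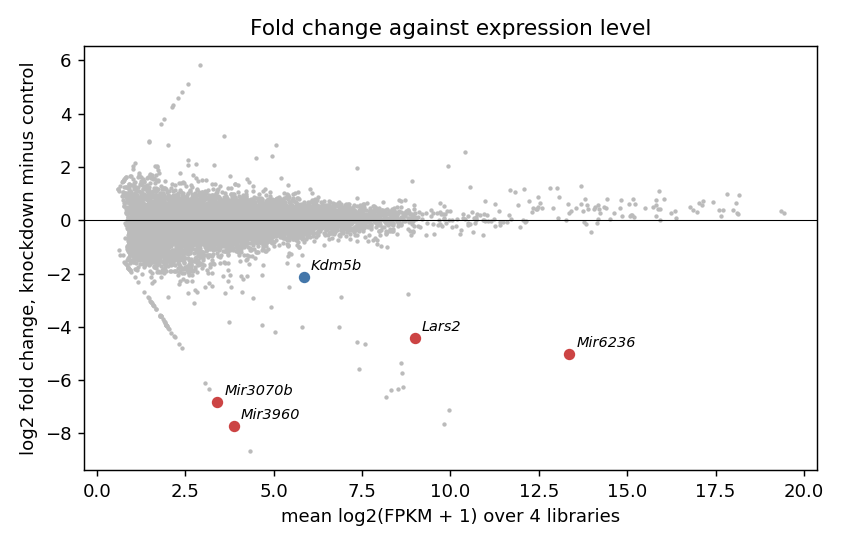
Log2 fold change (vertical axis, knockdown minus control) against mean log2(FPKM + 1) over the 4 libraries (horizontal axis) for 11784 loci, each a grey point. The 4 called loci are red and Kdm5b, at -2.14, is blue.

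The size of the group difference was set against the spread between libraries. By a mean difference of at least 2-fold with both knockdown libraries outside the control range, 162 loci were higher and 459 lower in knockdown, Kdm5b, Ezr and Tmsb4x among them. The total of 621 compares with 485 when the libraries were split by letter and 724 when control A and knockdown B were set against control B and knockdown A. The same 3 splits gave 4, 5 and 3 calls by limma, in that order. At an unadjusted limma p under 0.05 they gave 290, 214 and 507 loci. All lie under the 589 that chance gives, so that shortfall is not particular to knockdown against control. The SD of the log2 fold change was 0.65 for knockdown against control, 0.62 for the split by letter and 0.66 for the crossed split. With 3 splits no permutation p under 0.333 can be reached, so no test was made. Groups did not overlap at 31.9% of loci, where chance gives 33.3%. In each split more loci were lower on the side that held knockdown A. The counts were 459 against 162 for knockdown against control, 317 against 168 by letter and 555 against 169 for the crossed split. Quantile normalization gave 248 higher and 264 lower loci beyond 2-fold, a more even split. The counts were 137 higher and 187 lower without knockdown replicate A, and 805 and 1803 without knockdown replicate B. The surplus of lower loci was thus far larger in knockdown A than in knockdown B. The median half-width of the 95% interval was 0.90 on the log2 scale, and at 32.8% of loci the whole interval lay within 1 log2 unit of 0.

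Knockdown libraries did not group apart from control libraries. Pearson's r across loci, which are not independent replicates, was 0.940 between the 2 controls and 0.890 between the 2 knockdown libraries. Knockdown replicate B correlated with control replicates A and B at 0.941 and 0.957, while knockdown replicate A correlated with them at 0.867 and 0.891. Between the knockdown libraries 21.7% of loci differed by at least 2-fold, against 7.20% between the controls. By expression level, the median log2 fold change was -0.26 in the lowest of 5 equal groups of loci, -0.13, -0.04 and 0.01 in the next 3, and 0.07 in the highest. In the lowest group the median against the control mean was -0.56 in knockdown replicate A and -0.05 in knockdown replicate B.

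Groups of genes fixed beforehand were then compared. The endoderm list was lower by camera (6 tested of 12 listed, median log2 fold change -0.83, camera adjusted p = 0.00676), with 6 of 6 members on the lower side and 4 with both knockdown libraries below both controls. This call was lost with an estimated correlation (adjusted p = 0.962) and with fry (adjusted p = 0.114). Cubn stood at 4.23 and 7.39 FPKM in controls and 0.27 and 0.34 FPKM in knockdown, and Dab2, an endocytic adaptor, at 2.27 and 3.16 FPKM in controls and at 0 and 0.92 FPKM. The basement membrane gene Lama1 stood at 27.6 ± 4.14 and 14.9 ± 1.5 FPKM (SD, n = 2 each), and the transcription factor Gata4 at 1.84 and 1.45 FPKM in controls and at 0 and 1.25 FPKM in knockdown. Lamb1, named after its values were seen, had a log2 fold change of -0.08. The p53 target list was higher by camera (17 tested, median 0.31, camera adjusted p = 0.0182), with 12 members on the higher side, a call also lost with an estimated correlation (adjusted p = 0.962) and with fry (adjusted p = 0.948). Perp, a desmosome protein, had a log2 fold change of 1.05, Ei24 of 0.77 and Btg2, an antiproliferative factor, of 0.59, while Gdf15, a secreted stress factor, stood at -1.68. No member of either list passed limma over all genes; adjusted over the list alone, 1 endoderm gene (Cubn) and 0 p53 targets did. The endoderm call ended without control replicate B (median -0.96, camera adjusted p = 0.108) and without knockdown replicate B (median -1.07, camera adjusted p = 0.339), where the median was larger in size than with all libraries. The p53 call ended without control replicate B (median 0.14), knockdown replicate B (median 0.32) and knockdown replicate A (median 0.22). It also ended with quantile normalization (camera adjusted p = 0.113), with eBayes without trend (0.0631) and with the replicate block (0.0521).

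**Figure D3:**
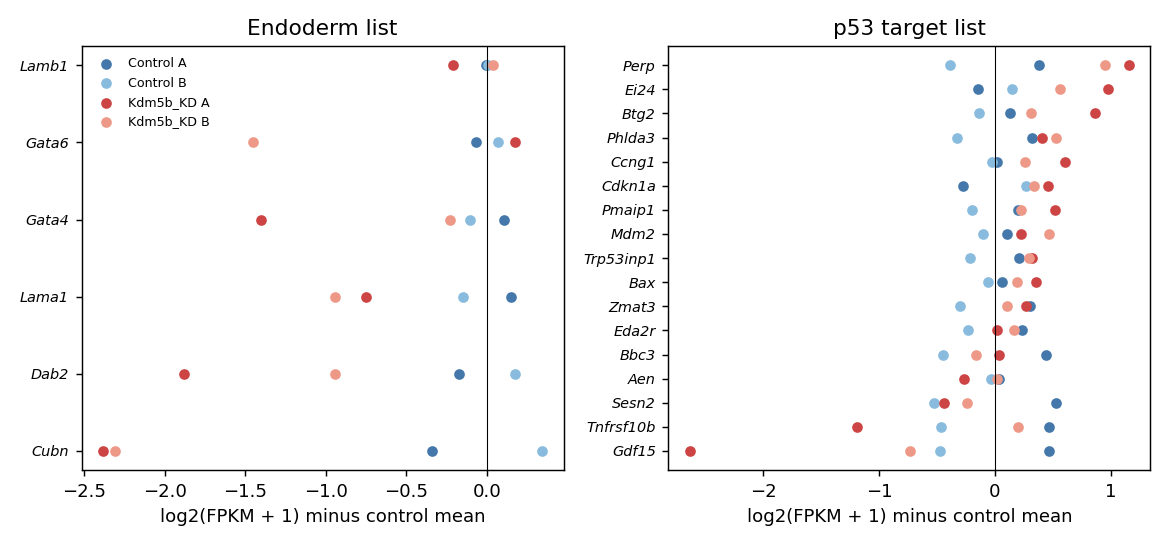
Log2(FPKM + 1) of each library minus the control mean (horizontal axis) for the tested members of the endoderm and p53 target lists; each point is 1 library, blue for control and red for knockdown. Cubn, at a log2 fold change of -2.34, and Gdf15, at -1.68, lie farthest below the controls.

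The other 16 lists with at least 3 tested members did not pass camera with all 4 libraries, and adjusted over the list alone 0 of their genes were called. Of 27 pluripotency genes 14 were on the higher and 13 on the lower side (median 0.03, camera adjusted p = 0.958); Klf5 stood at -0.99 (standard error 0.33), Klf4 at -0.84 (0.24) and Dppa3 at 0.97 (0.35). Of 13 genes of the H3K4 methyltransferase complexes 10 were on the lower side (median -0.11), with Setd1a at -0.52 and Wdr5 at -0.44. The 16 Polycomb genes divided 8 to 8 (median 0.03), with Ezh2 at 0.49 and Kdm2b at -0.46, and of 16 elongation and H3K36 methylation genes 9 were higher (median 0.08), with Nsd2 at -0.52 and Ctr9 at 0.42. The 25 cell cycle genes had a median of -0.01, with Cdk2 at -0.71 and Ccnd1 at 0.65. The 6 genes tied to KDM5B elsewhere had a median of -0.01, with Cdkn1b at -0.62 and Cdkn1a at 0.40. Medians were -0.12 for 7 ectoderm genes (Sox3 at 0.96, Fgf5 at -0.55), -0.14 for 6 trophoblast genes (Krt18 at -1.61, Gcm1 at 0.88) and -0.47 for 9 germline genes (Mael at 1.35, Hormad1 at -1.26). They were -0.33 for 13 stress response genes (Ddit3 at -1.33, Chac1 at -1.15), -0.21 for 10 interferon response genes (Stat2 at -0.74, Oas1a at -0.69) and -0.01 for 9 immediate early genes (Fos at -0.98, Srf at -0.88). Of 15 replication-dependent histone genes 10 were on the lower side (median -0.16, camera adjusted p = 0.192), with H3c2 at -1.08 and H3c13 at -0.57. At the preset correlation of 0.01 this list passed camera without control replicate B (median -0.24, camera adjusted p = 0.00199) and without knockdown replicate A (median -0.25, camera adjusted p = 0.0247). Its estimated correlation was 0.42, and with all 4 libraries the adjusted p was 0.962 with an estimated correlation and 0.948 with fry. The 4 fibroblast genes had a median of -0.85 (camera adjusted p = 0.776, Acta2 at -1.48, Thy1 at -1.19). The 6 abundant noncoding RNAs had one of 0.01 (Neat1 at -0.32, Malat1 at -0.21), and the 4 other H3K4 demethylases one of 0.05. Among the members named above, knockdown and control libraries overlapped for Setd1a, Ctr9, Fgf5, Hormad1, Ddit3, Chac1, Oas1a, Srf, Neat1 and Malat1. Setd1a, Fgf5, Hormad1, Ddit3, Oas1a and Srf lay below both controls in knockdown A only. Hormad1 stood at 6.56 and 6.01 FPKM in the controls and at 0.23 and 6.46 FPKM in knockdown A and B. Ddit3 and Chac1 stood at 63.4 and 76.7 FPKM in control A but at 15.9 and 19.6 FPKM in control B. Leaving out 1 library at a time turned the sign of the median in 12 of these 16 lists. Without knockdown replicate A it turned to 0.12 for the H3K4 methyltransferase complexes, 0.15 for ectoderm, 0.09 for trophoblast, -0.09 for pluripotency and -0.02 for Polycomb genes. Without knockdown replicate B it turned to 0.24 for ectoderm, 0.04 for stress response, 0.03 for immediate early, 0.01 for cell cycle and -0.12 for abundant noncoding RNA, and was -0.33 for the H3K4 methyltransferase complexes. Without control replicate A it turned to 0.04 for those complexes, 0.13 for genes tied to KDM5B elsewhere, -0.10 for pluripotency, -0.03 for other H3K4 demethylases and -0.01 for elongation, and was -0.44 for immediate early. Without control replicate B it turned to 0.02 for cell cycle and -0.18 for abundant noncoding RNA, and was -0.69 for stress response, -0.44 for immediate early and -0.38 for genes tied to KDM5B elsewhere. The other 4 kept their sign, between -0.50 (without control B) and -0.12 (without knockdown A) for germline and -0.34 (without knockdown B) and -0.05 (without knockdown A) for interferon response. They ranged between -1.38 (without control B) and -0.06 (without control A) for fibroblast genes and -0.25 (without knockdown A) and -0.06 (without control A) for histones. Median, mean and camera direction differed in sign for pluripotency (mean -0.05, down), other H3K4 demethylases (mean -0.0044, up), genes tied to KDM5B elsewhere (mean -0.05, up), ectoderm (mean 0.01, up), germline (mean -0.12, up) and abundant noncoding RNA (mean -0.03, up). Mesoderm, with 2 tested genes (Eomes at -0.09, Bmp4 at 0.04), and two-cell-like genes, with 0, were not tested as lists. The series also names promoters inside genes, which values per locus do not resolve and which were not analysed here.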

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

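The settings of a mean of at least 20 estimated fragments and of estimated library weights were added after seeing the data. Kdm5b kept its direction and stayed short of the limma threshold under all 16 alternatives, with log2 fold changes from -2.40 to -1.87 and limma adjusted p from 0.0540 to 1. The 4 calls, all lower, became 1 with no filter on low values, Mir3960, and 2 with eBayes without trend, Mir3960 and Mir3070b. Lars2 was not called in those settings (limma adjusted p = 0.413 and 0.390). Lars2 was the 1 call when small noncoding RNA genes were left out and the 1 call with at least 20 estimated fragments. Leaving out 1 library gave 0 to 134 calls, of which 0 to 119 lower and 0 to 15 higher; the lone library left in a group is then assumed to vary like the other group. The letters A and B are not stated to pair the libraries, and deviations of same-letter libraries correlated across loci at -0.07; with the replicate block there were 7 calls, 7 of them lower, and 1 called list, endoderm, with a camera adjusted p of 0.0521 for p53 targets. The 621 loci beyond 2-fold became 229 with a mean of at least 5 FPKM (68 higher, 161 lower), 336 with at least 20 estimated fragments (68 higher, 268 lower) and 1525 with a log2 difference of at least 0.58 (574 higher, 951 lower). The higher ones were 270 and 285 with pseudocounts of 0.1 and 0.01, and quantile normalization gave 248 higher and 264 lower. Without 1 library the total ranged from 324 to 2608 (137 to 805 higher, 187 to 1803 lower). The SD of the fold changes, 0.65, was 1.02 and 1.42 with pseudocounts of 0.1 and 0.01, and 0.56 to 1.04 without 1 library. Of the 2 called lists, 1, p53 targets, passed with a mean of at least 5 FPKM, where endoderm had fewer than 3 members and was not tested, 1 passed with quantile normalization, 1 with eBayes without trend, 0 with an estimated correlation, 0 with fry, and 0 to 2 without 1 library, the replication-dependent histones counted among these without control B and without knockdown A. The mean correlation between groups, 0.914, was 0.858 with a pseudocount of 0.1. Among named and called genes 388 of 405 recomputed values kept direction and side of the threshold, 16 lost a call and 1 turned: Kdm5c, which ranged from -0.15 to 0.020 without 1 library. With upper-quartile scaling the medians by level were -0.27, -0.14, -0.06, -0.01 and 0.06 from the lowest group to the highest, where the values as deposited gave -0.26, -0.13, -0.04, 0.01 and 0.07. Fewer loci were tested under the stricter filters and fewer libraries when 1 was left out; otherwise the cause was not tested. At the estimated depths, a set dispersion of 0.04 and 2 libraries per group, at most 9% of simulated 2-fold changes were called. Depth was not varied, so its part in this was not tested.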

Other observations

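In this part the tests of Lars2 and Mir6236, the test of the endoderm list without knockdown replicate A and the comparisons of zeros with counting alone and with thinning were chosen after the result was seen; the second endoderm list and the test of repeated molecules were written before their values were looked at. Genes for ribosomal proteins (79 tested) had a median log2 fold change of 0.17. Of these genes, 60 were on the higher side and 19 had both knockdown libraries above both controls. The median was 0.11 and 0.24 without knockdown replicates A and B, and -0.0019 and 0.29 without control replicates A and B. For 47 complex I genes named Nduf the median was 0.11, with 10 above both controls in both libraries, and for 14 Cox genes 0.18, with 3. Without knockdown replicate A those medians were -0.01 and 0.02, and without control replicate A -0.0046 and 0.05. Without knockdown replicate B they were 0.39 and 0.22, and without control replicate B 0.31 and 0.22. Among lists matched on level the 3 families stood at the 95, 81.2 and 83.8 percentile. They were chosen after the data were seen, and each median over all libraries kept its sign with upper-quartile scaling and quantile normalization.

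Lars2 and Mir6236 were lower in both knockdown libraries, with log2 fold changes of -4.44 and -5.03, and both were higher in control B than in control A. A line through control A and the knockdown mean predicted 3257 FPKM of Lars2 in control B from Mir6236, and missed the observed 3176 FPKM by 2.56%, so a shared source of reads that feeds both loci is a candidate explanation. Their transcripts held 0 matches of at least 50 bases at 95% identity to the ribosomal precursor transcripts Gm42418, Gm26917 and AY036118. Shorter matches were not counted, so this covers long shared stretches only and does not settle whether those transcripts were the source. The 28S ribosomal RNA sequence was not used here, so carried-over 28S RNA stays open and untested. A lower level of Lars2 RNA after knockdown stays open too.

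The endoderm list was lower by camera with all 4 libraries, a call lost with an estimated correlation (adjusted p = 0.962), with fry (0.114) and without control B (0.108) or knockdown B (0.339). The greater number of zeros in knockdown replicate A does not account for it, since without that library the median of the 6 tested members was -0.94. If knockdown cultures held fewer extraembryonic endoderm-like cells, other markers of those cells may be lower as well: the 9 tested genes of a second list of 15 had a median of -0.68, at the 1.22 percentile of 10000 random lists matched on level, with 6 on the lower side. The middle member, Foxq1, stood at 2.08 and 2.13 FPKM in the controls and at 1.97 and 0.27 FPKM in knockdown A and B. Nid2 and Tfpi, the members with the highest values, stood at -0.03 and 0.33, and the next, Lrp2, at -0.85. The percentile was 0.4, 4.77 and 0.04 without control A, control B and knockdown A. Without knockdown replicate B the percentile was 29.5, past the limit that had been set beforehand as counting against this explanation. By contrast, 10 type IV collagen and laminin genes, chosen after the data were seen, had a median of -0.12 (41.4 percentile). That median was -0.13 and -0.41 without controls A and B, and -0.23 and -0.18 without knockdown A and B. The 4 tested fibroblast genes had a median of -0.85 (camera adjusted p = 0.776), and of -0.06 without control A. The percentile describes these 4 libraries, so a difference between cultures unrelated to the knockdown cannot be separated from one due to it.

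Knockdown replicate A listed more loci at 0 than the other libraries. Of 757 loci with 5 to 10 estimated fragments in control B, 64.3% stood at 0 there, against 9.11% in knockdown B and 5.68% in control A. These shares are 91.7, 46.7 and 35.1 times what counting alone gives. That benchmark takes the count in control B, by which the loci were chosen, as the true level. Chance in that choice raises the other libraries above the benchmark, so the multiples overstate the excess of zeros by an amount not estimated. Thinning knockdown B to the depth of knockdown A would give at most 15.5% at 0. The observed share is 4.14 times that, which argues against lower depth by itself. The mean FPKM of these loci, zeros included, was 95.4% of that in knockdown B. FPKM is scaled to depth, so similar means would also come from lower depth alone and do not favour repeated molecules. Fewer distinct molecules, each read several times, stays a candidate explanation that these values cannot decide. Loci above 0 stood 2.57 times higher in the median. That value largely follows from the mean and the share at 0, so it adds no separate support. No biological explanation was tested for this pattern, which lies in 1 library.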
